A study of Mus musculus with 6 samples.

How the data were processed

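The series holds 6 mouse RNA-seq libraries from the embryonic striatum at E15.5 (embryonic day). Per the labels, cells with strong green fluorescence were sorted from embryos that carry Cre recombinase and EGFP under the Dlx5/6 enhancer, which is active in the ganglionic eminences. The WT group carries an intact Pqbp1 allele and the cKO group a floxed allele that Cre can delete, each on the single X chromosome of a male. The labels give 3 libraries per group, numbered 1 to 3 in each. Nothing in the labels says that the libraries of a group came from separate embryos or litters, so p-values measure the spread between these libraries, which may be partly technical.

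Per the labels' protocols, total RNA was extracted with RNAiso Plus and libraries were made with a SMARTER mRNA-seq kit, which amplifies cDNA by PCR from small amounts of RNA. The deposited table holds raw read counts per gene, as whole numbers, for 38175 Ensembl gene identifiers. The submitters' processing notes name Bowtie, TopHat, Cufflinks, Cuffdiff, R 3.1.1 and the genome build GRCm38, without saying which step each served. The program that made the counts, its annotation and its use of strand are not given in the sources used here. Reads of overlapping genes, antisense pairs and near-identical copies therefore cannot be told apart. No molecular identifiers were described, so reads can be PCR copies of 1 molecule, and every interval and detection floor given here covers counting error only.

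The deposited table also holds a signal per gene that the authors made by averaging normalized counts over all libraries, with no tool named. From the values, it equalled the mean of counts divided by DESeq2 size factors, within a relative tolerance of 1e-06, for all 38175 genes, and was used only for that check. In 26 rows the symbol had been turned into a date and in 1916 rows none was given. Through the identifiers, 26 and 1827 of these were given their symbols from GENCODE M21. In all, 38086 identifiers matched that annotation, which is built on GRCm38 and gave the coordinates.

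Library totals were 12263846, 29499156 and 35046431 counts for WT replicates 1, 2 and 3, and 26429191, 11475511 and 34944616 counts for cKO replicates 1, 2 and 3. A count of 3 corresponds to 0.213 CPM, counts scaled to a common library total, in the shallowest WT library and 0.253 CPM in the shallowest cKO library. These values served as the per-library detection floor. CPM values are scaled by TMM factors over the tested genes.

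The main test was edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr with the group factor, glmQLFit with robust estimation and glmQLFTest for cKO minus WT. P-values were adjusted by the Benjamini-Hochberg method over the 17425 genes kept, with a threshold of 0.05. Standard errors of log2 fold changes are those implied by the F statistic. On simulated counts with the means, library sizes and per-gene dispersions of these libraries, this test run on 16085 genes recovered 0% of genes changed 4-fold, 46.3% of genes changed 16-fold and 74.2% of genes changed 64-fold. With a dispersion of 0.05 in place of the real ones it recovered 100% at each of those sizes, on 17192 genes. DESeq2, run on 17425 genes of the simulation with the real dispersions, recovered 16.4%, 80.6% and 93.9% at these sizes with 114 false calls, where edgeR made 1. The changed genes numbered 67, 67 and 66 at these sizes and were drawn only from genes above a set expression level. Genes were simulated independently of each other, without the library-wide trends of the real data.

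Gene lists were fixed before the data were examined. They cover progenitors, cell cycle phases, striatal and other neurons, signalling, splicing, metabolism, other cell types and RNA quality. The 36 lists with at least 5 tested genes were compared with the remaining genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and adjusted over the lists. Members were also adjusted over the list alone. A list score is the mean over its members of log2 CPM (prior count 2) minus the gene's mean over all 6 libraries.

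Genes are named by a rule also fixed before the data were examined. It takes Pqbp1, then the 8 largest changes in each direction among genes past the threshold with a mean CPM of at least 5, groups that do not overlap and a named symbol, and up to 4 members of each list with the smallest p. No gene passed, so the places were filled, as the rule provides, by the genes with the smallest p in each direction. The rule leaves open whether its conditions on level, overlap and name hold for these, and they were kept. Other genes are named as markers of a cell type, or as chosen after their values were seen.

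Alternatives planned before the data were examined were other normalizations, other filters on low counts, DESeq2 1.42.0, limma-voom with and without quality weights, other thresholds, the replicate number as a block, leaving out each library, and for the lists an estimated correlation and fry. A further 4 were added after the data were examined: leaving out both libraries numbered 2, a batch term from ribosomal RNA content (above or below 1% of counts), and per-library GC content and length trends (natural splines with 4 degrees of freedom) removed through offsets, without and with the replicate block. GC content was known for 99.9% of tested genes.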

Results

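Gene expression was measured by RNA-seq in cells with strong green fluorescence sorted from mouse embryos at E15.5, which the labels call striatal intermediate progenitors. There were 3 libraries labelled WT and 3 labelled cKO, the latter from embryos in which Cre under the Dlx5/6 enhancer can delete a floxed Pqbp1 allele. The question, from the series title, is how loss of PQBP1 shifts progenitors between dividing and differentiating. Library totals ranged from 11475511 counts (cKO replicate 2) to 35046431 counts (WT replicate 3).

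The sorted cells had the transcripts of ventral forebrain cells in all 6 libraries. Gad2, which makes GABA, lay between 352 CPM in cKO replicate 2 and 584 CPM in WT replicate 2. Gad1, the other gene of GABA synthesis, was less even, with 18.3 CPM in cKO replicate 2 and 97.5 to 237 CPM elsewhere. The homeobox gene Dlx1 averaged 393 ± 103 CPM in WT and 303 ± 68.8 CPM in cKO (SD, n = 3 each). Bcl11b, a transcription factor of striatal projection neurons, averaged 740.5 ± 229 CPM in WT and 1004 ± 487 CPM in cKO (SD, n = 3 each). The proliferation marker Mki67 was detected in each library, from 139 CPM in cKO replicate 1 to 372 CPM in WT replicate 2.

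Libraries did not group by label. The closest pair was WT replicate 3 and cKO replicate 3, with a Pearson correlation of 0.962 across genes in log2 CPM. The most distant pair was WT replicate 2 and cKO replicate 2, at 0.668. The first principal component, with 44.9% of the variance, set cKO replicate 2 apart, and the second, with 36.5%, set WT replicate 2 apart. In WT replicate 2, 16551 genes had a read, against 25484 to 29534 in the libraries other than the pair numbered 2, and cKO replicate 2 had 19986. In WT replicate 2 the 771 genes with a GC content above 60% had a median deviation of -1.26, in log2 CPM, from their means over the 6 libraries. The other libraries had 0.18 (cKO replicate 3) to 0.63 (cKO replicate 1). The trend of cKO replicate 2 was opposite, from -0.53 for genes with a GC content up to 40% to 0.19 above 60%. Tubb3, a neuronal tubulin chosen after its values were seen, had 0.493 CPM in WT replicate 2 and 827 to 2076 CPM elsewhere. The chi-square per degree of freedom between libraries of one group was at least 264, so none was a second deposit of another. Ribosomal RNA-like genes took 7.21% of counts in WT replicate 1, 3.91% in cKO replicate 1 and 2.33% in cKO replicate 2. In WT replicates 2 and 3 and cKO replicate 3 they took 0.199%, 0.205% and 0.252%. The exact 95% binomial intervals of these shares are narrower than 0.03 percentage points. A limit of 1%, set after the data were examined, divides the libraries into 3 with high and 3 with low ribosomal RNA content. These are called batches here, and both hold libraries of each label. No label gives a batch, and similarity between libraries did not follow this division throughout. In log2 CPM, cKO replicate 1 correlated at 0.924 and 0.742 with WT replicate 1 and cKO replicate 2 of its batch. It correlated at 0.926 and 0.928 with WT replicate 3 and cKO replicate 3 of the other batch.

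**Figure D1:**
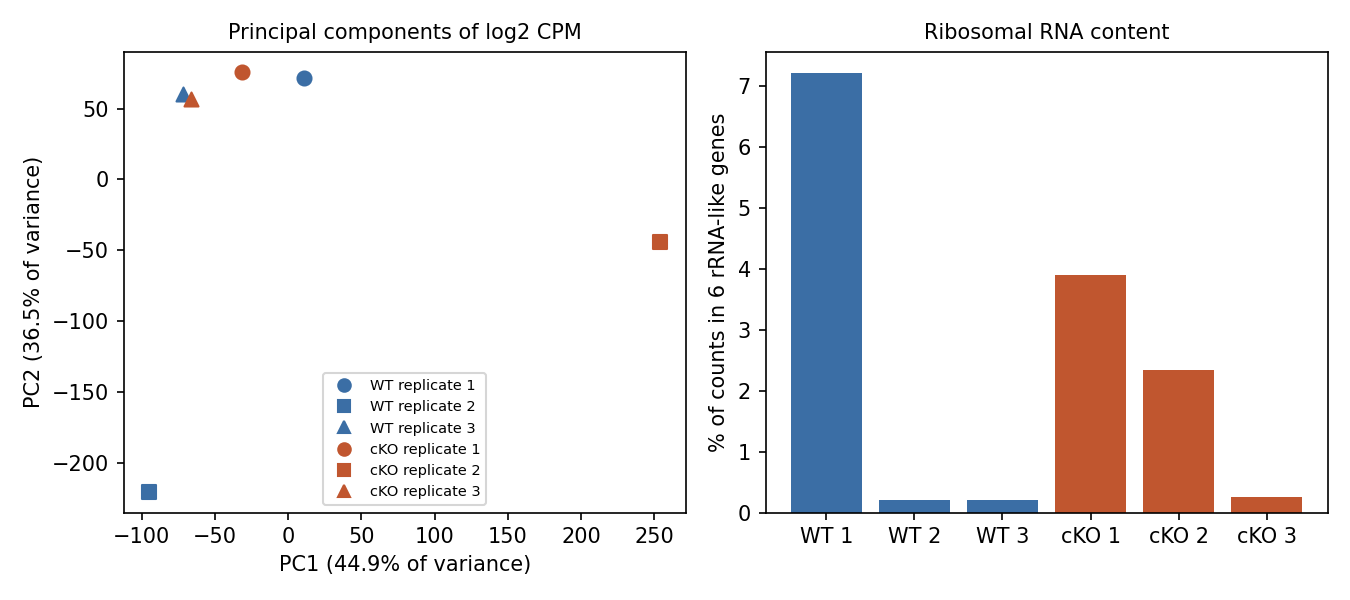
Left, principal components 1 and 2 of log2 CPM, with each point a library, coloured by its label and shaped by its replicate number, where cKO replicate 2 and WT replicate 2 stand apart. Right, bars of the percentage of counts in 6 ribosomal RNA-like genes per library, which exceed 2% in 3 libraries.

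Pqbp1, the targeted gene, was not lower in the libraries labelled cKO. PQBP1 is a polyglutamine-binding protein with roles in transcription and splicing, and its gene (ENSMUSG00000031157) lies on the minus strand of chromosome X from 7894519 to 7899269 in GRCm38. The libraries labelled WT had 99.9, 119 and 403 CPM in replicates 1, 2 and 3, and those labelled cKO 248, 322 and 310 CPM. The means were 207 ± 170 CPM and 294 ± 40.01 CPM (SD, n = 3 each). The log2 fold change of cKO over WT was 0.50 with a standard error of 0.63, within the spread between libraries (adjusted p = 0.9999, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In the high ribosomal RNA batch the WT library had 99.9 CPM and the cKO libraries 248 and 322 CPM. In the low batch the WT libraries had 119 and 403 CPM and the cKO library 310 CPM, so the order did not hold within that batch. The log2 fold change was 0.12 without WT replicate 2, 0.16 without WT replicate 1, 0.32 without cKO replicate 3 and 1.44 without WT replicate 3, and none passed. Counts cover the whole gene, so reads from parts that Cre leaves in place are included and the level does not settle a library's genotype. Directions below are therefore those of the labels.

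Genes that differ between the sexes set 1 library apart. Xist, the X-inactivation transcript of female cells, had 126 CPM in WT replicate 2 and at most 0.992 CPM in each of the other libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no read in WT replicate 2. Eif2s3y had between 31.7 and 63.3 CPM in the other libraries. The labels describe male embryos in both groups, and WT replicate 2 did not have the expression pattern of a male.

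**Figure D2:**
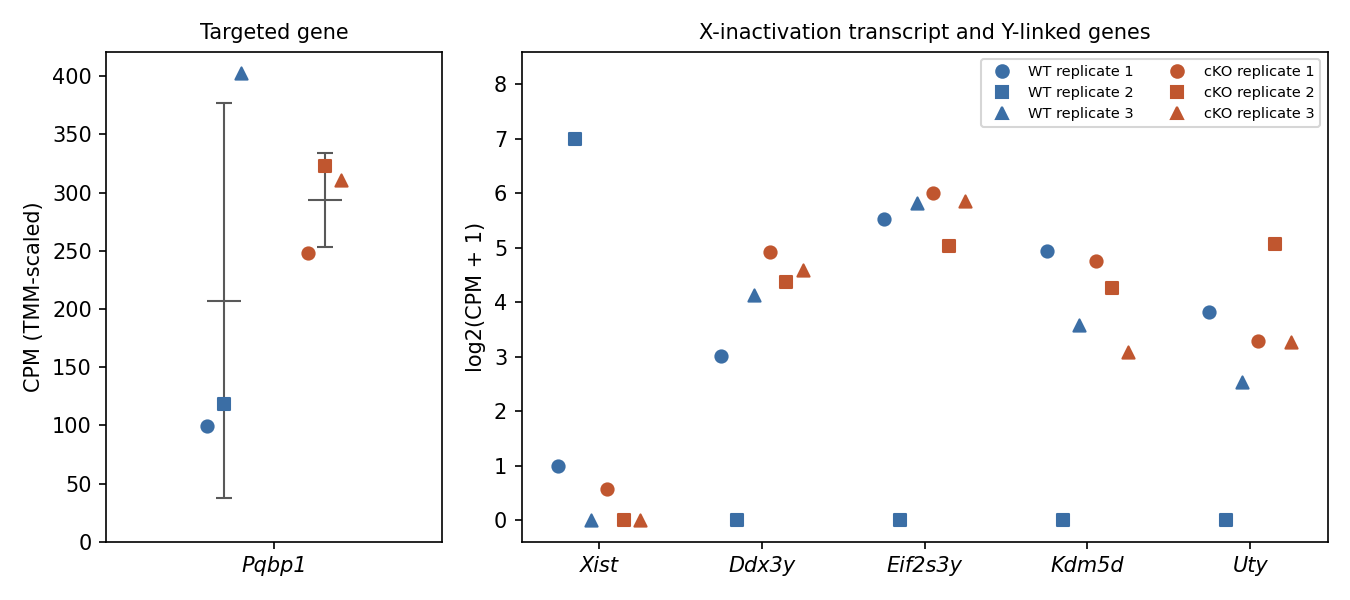
Left, Pqbp1 in CPM per library (points) with the group mean and SD, from 99.9 to 403 CPM in WT and from 248 to 322 CPM in cKO. Right, log2(CPM + 1) of Xist and 4 Y-linked genes per library, where WT replicate 2 alone has high Xist and no Y-linked reads.

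Between cKO and WT, no gene passed the adjusted threshold in either direction. The edgeR test on 17425 genes called 0 genes higher and 0 lower, with 143 genes at an unadjusted p under 0.05, of which 122 were higher and 21 lower in cKO. DESeq2 called 50 genes, 45 higher and 5 lower, of which 41 had reads in cKO replicate 2 alone, and limma-voom called 0. Without the low-count filter edgeR called 59 genes, 54 of them higher, and 2 genes, Hist2h2aa1 and Ccnk, were also among the DESeq2 calls. The groups did not overlap for 579 genes, which is 3.32% of those tested, where chance alone gives 10%. Without both libraries numbered 2 the count stayed at 0.

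Among genes with lower values in the libraries labelled cKO, the smallest p belonged to Hist2h2aa1, a replication-dependent histone H2A gene (ENSMUSG00000064220, chromosome 3, 96245497 to 96246082). It had 19.9, 6.91 and 39.8 CPM in the WT libraries and no read in the 3 cKO libraries, which is at least 87.6-fold lower at a floor of 3 counts in the shallowest cKO library. Its adjusted p was 0.9999 by edgeR and 3.66e-09 by DESeq2. It has a near-identical neighbour, Hist2h2aa2, which had 0.356 CPM in WT and no read in cKO, so how reads were divided between the copies is uncertain. Ccnk encodes cyclin K, a partner of the kinases that act on RNA polymerase II (ENSMUSG00000021258, chromosome 12, 108179579 to 108203359). It had 22.8 ± 12.5 CPM in WT and 1.13 ± 1.05 CPM in cKO (SD, n = 3 each). The log2 fold change was -4.31 with a standard error of 1.05 (adjusted p = 0.9999 by edgeR, 0.0239 by DESeq2). The other lower genes called by DESeq2, named after their values were seen, were the protocadherin Pcdhb17 (6.07 CPM in WT and 0.0563 CPM in cKO, adjusted p = 0.00173), the pseudogene Gm12245 (4.66 and 0.298 CPM) and the antisense transcript Gm42893, with reads in WT replicate 1 alone. Lower calls of edgeR without the filter, named likewise, were Gm20390 (43.4 and 2.17 CPM), Tcte1 (15.1 and 0.246 CPM) and Qser1, with reads in WT replicate 3 alone. The other places of the rule went to Tmem170b, Mns1, Kctd9, Vma21, Ooep and Clp1, with log2 fold changes from -3.26 (Tmem170b) to -1.32 (Vma21), none past the threshold. Without WT replicate 2 those of Kctd9 and Clp1 went from -2.52 and -1.62 to -1.38 and -0.98.

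Among genes with higher values in the libraries labelled cKO, none passed in the filtered edgeR test, and 54 did without the filter. Zfp652 had 6.29 ± 3.81 CPM in WT and 26.0 ± 11.8 CPM in cKO (SD, n = 3 each), a log2 fold change of 2.05 with a standard error of 0.76. Ap5s1, a subunit of an adaptor complex, had 9.56 ± 7.84 CPM in WT and 37.4 ± 6.19 CPM in cKO (SD, n = 3 each). Scrt1, a transcriptional repressor of newborn neurons, had 2.60 ± 1.71 CPM in WT and 14.1 ± 10.4 CPM in cKO (SD, n = 3 each). Rbm45, Zbtb37 and Sall3 had log2 fold changes of 4.31, 1.82 and 2.22, of which that of Sall3 was 0.84 without cKO replicate 2. The higher DESeq2 calls with reads in more than 1 library, named after their values were seen, were Ttc34, 4933438K21Rik, Trbv12-1 and Gm14762, all without a read in WT. Ttc34 had 0.513, 2.365 and 0.9235 CPM in cKO replicates 1, 2 and 3 (adjusted p = 0.0483 by DESeq2 and 0.9999 by edgeR), and the other 3 had 12.6 to 17.7 CPM in cKO replicate 2 and at most 1.57 CPM elsewhere. For St14 and Rab11fip1 most reads came from 1 library, cKO replicate 2, with 29.8 and 38.0 CPM against at most 0.821 CPM in any other.

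Cell cycle genes were lower as a group in the libraries labelled cKO. Of 56 tested genes of G2 and M phase, 51 had a log2 fold change below 0, and the median was -0.40 (camera adjusted p = 9.32e-05, and adjusted p = 0.951 with an estimated correlation). Of 50 genes of S phase 35 were below 0, with a median of -0.41 (camera adjusted p = 0.00119, and adjusted p = 0.951 with an estimated correlation). The median over all tested genes was 0.01. No member passed over all genes or adjusted over the list alone. Birc5, which encodes survivin, averaged 552.5 ± 405.5 CPM in WT and 275 ± 168 CPM in cKO (SD, n = 3 each). Cks1b, a regulatory subunit of cyclin-dependent kinases, averaged 566 ± 507 CPM and 215 ± 182 CPM, and Rfc4, of the clamp loader of DNA replication, 221 ± 178.5 CPM and 98.0 ± 67.3 CPM (SD, n = 3 each). These 3 means rested on WT replicate 2, without which the log2 fold changes of Birc5, Cks1b and Rfc4 went from -1.01, -1.40 and -1.17 to -0.38, -0.52 and -0.39, and WT replicate 1 lay below cKO replicates 1 and 3 in each. Cdc25c went the other way, with a log2 fold change of 1.44 and 112 CPM in cKO replicate 2, and 0.07 without that library. The G2 and M score was -0.02, 0.03 and 0.67 in the WT libraries and -0.06, -1.04 and 0.41 in the cKO libraries. The library with the score of -1.04, cKO replicate 2, also had the lowest score of mitochondrially encoded genes, -2.44. The score of cKO minus WT was -0.53 within the high ribosomal RNA batch and 0.06 within the low batch for G2 and M phase, and -0.55 and 0.04 for S phase, so the difference did not hold within the low batch. Without cKO replicate 2 the high-batch values were -0.04 for both lists, and without WT replicate 2 the low-batch values were -0.26 and -0.22. With batch as a term the medians were -0.24 for G2 and M phase and -0.20 for S phase (adjusted p = 0.00803 and 0.0292). Without WT replicate 3 both calls were lost (medians -0.05 for G2 and M phase and -0.24 for S phase, adjusted p = 0.0759 for each), and without cKO replicate 1 that of S phase was lost at a median of -0.46 (0.0521). Without cKO replicate 2 the medians were -0.13 and -0.20 (adjusted p = 0.0234 and 0.0196), and without cKO replicate 3 they were -0.83 and -0.64. Without both libraries numbered 2 they were called at 0.0388 and 0.04997. All p-values of the batch term and of left-out libraries in this paragraph used the preset correlation of 0.01. In the main setting the estimated correlation was 0.19 for G2 and M phase and 0.07 for S phase, and neither list was called with it.

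Genes of oxidative phosphorylation were also lower as a group in the libraries labelled cKO, with 65 of 74 below 0 and a median log2 fold change of -0.37 (camera adjusted p = 1.24e-04, and adjusted p = 0.951 with an estimated correlation). Cox7c, a subunit of cytochrome c oxidase, had 2841 CPM in WT replicate 2 and between 358 and 756 CPM in the other libraries. Ndufa1, of complex I, had 836 CPM in WT replicate 2 and 103 to 203 CPM elsewhere. No member passed over all genes or adjusted over the list alone. Without WT replicate 2 the median was -0.11 and the direction of the test turned to higher (adjusted p = 0.999), and without cKO replicate 1 the call was lost at a median of -0.33 (0.151). It was also lost without both libraries numbered 2 (median -0.08, adjusted p = 0.817) and with the batch term (median -0.11, 0.625). The median was -0.69 without WT replicate 1 and -0.65 without cKO replicate 3. The score was -0.65, 0.70 and 0.36 in WT replicates 1, 2 and 3 and -0.33, -0.23 and 0.14 in the cKO replicates. The groups thus overlapped, with WT replicate 1 the lowest of all. Within the batches the score of cKO minus WT was 0.38 at high and -0.40 at low ribosomal RNA content, and -0.22 at low content without WT replicate 2.

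**Figure D3:**
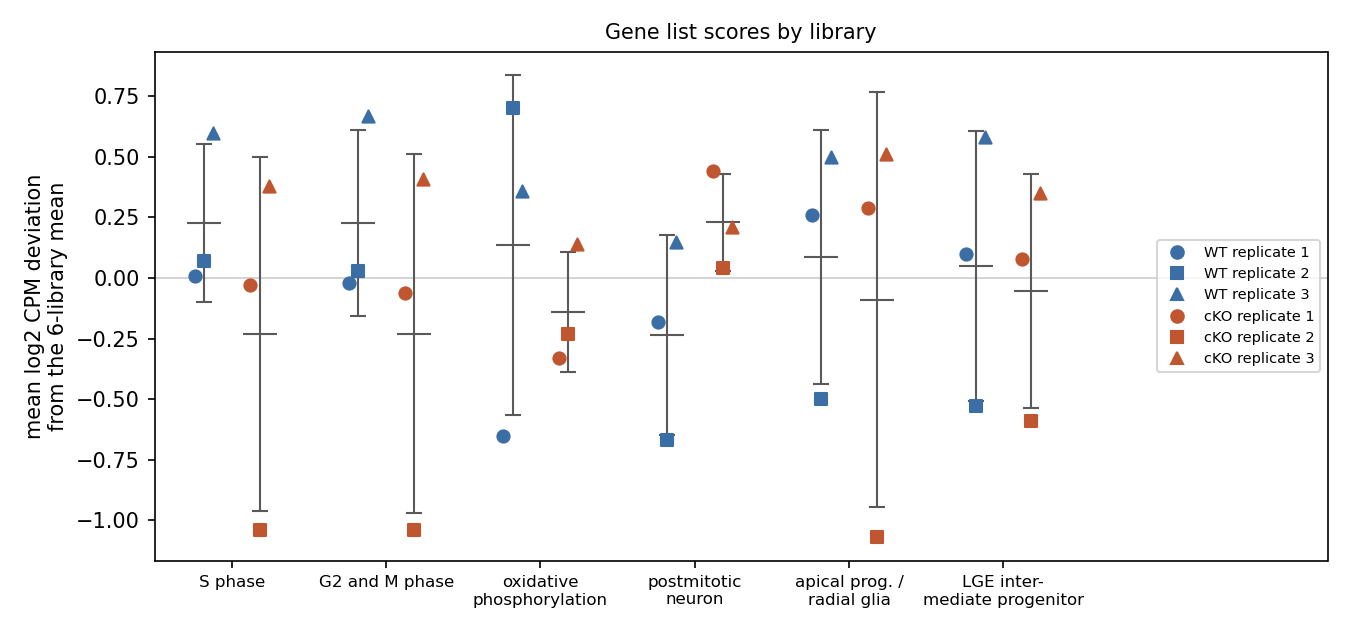
Scores of 6 gene lists per library (points), as the mean log2 CPM deviation from the mean of the 6 libraries, with the group mean and SD. The S phase and the G2 and M phase scores of cKO replicate 2 are both -1.04, and the highest scores, 0.60 and 0.67, are those of WT replicate 3.

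Genes of postmitotic neurons had higher values in the libraries labelled cKO but did not pass. The list had 24 of 34 members above 0, a median log2 fold change of 0.18 and a camera adjusted p of 0.107. Mapt, which encodes the microtubule protein tau, had 235 ± 24.3 CPM in WT and 535 ± 192 CPM in cKO (SD, n = 3 each), and all cKO libraries lay above all WT libraries. The log2 fold change of Mapt was 1.19 with a standard error of 0.51 (adjusted p = 0.9999 by edgeR). The list score of cKO minus WT was 0.42 and 0.47 within the batches of high and low ribosomal RNA content, the latter 0.06 without WT replicate 2. Without both libraries numbered 2 the list was called higher (adjusted p = 0.0299), while the median was 0.04 both without cKO replicate 1 (0.625) and with GC and length trends removed (0.457).

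Lists of progenitor and striatal identity were not called. In 24 of the 33 lists not called, leaving out 1 library turned the sign of the median log2 fold change or brought it to 0. Genes of apical progenitors had a median of -0.14 (adjusted p = 0.352; -0.42 to 0 without single libraries), with Pax6 at 44.1 ± 25.6 CPM in WT and 23.0 ± 14.7 CPM in cKO (SD, n = 3 each). The log2 fold change of Pax6 was -0.94, and -0.40 without WT replicate 2. Genes of intermediate progenitors of the lateral ganglionic eminence had a median of 0.02 and a mean of -0.04 (adjusted p = 0.567), and medians of -0.35 without cKO replicate 3 to 0.20 without WT replicate 3. Inhibitors that act at cell cycle exit had a median of 0.07 (adjusted p = 0.9955), and Cdkn1c, which encodes p57, had a log2 fold change of 0.95 with a standard error of 0.66, and 0.46 without WT replicate 2. Genes shared by striatal projection neurons had 19 of 27 members above 0 and a median of 0.19 (adjusted p = 0.645). The direct pathway list had a median of 0.16 and a mean of -0.05, and the indirect pathway list a median of 0.07, with camera directions below 0 for both (adjusted p = 0.910 and 0.963). Ebf1, a direct pathway factor, averaged 84.8 ± 54.6 CPM in WT and 120 ± 27.4 CPM in cKO (SD, n = 3 each). Without single libraries the medians of the exit inhibitors lay between -0.23 and 0.10, and those of the shared, direct and indirect lists at 0 to 0.30, -0.16 to 0.29 and -0.23 to 0.28. GABAergic identity genes had a median of -0.05 (adjusted p = 0.834), which was 0.02 with library size as the scale. With upper-quartile factors the medians of intermediate progenitors, exit inhibitors and the indirect pathway were -0.06, -0.03 and -0.08.

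Signalling and RNA processing lists were not called either. Notch pathway genes had a median log2 fold change of 0.18 (adjusted p = 0.699), with Maml3, a coactivator of Notch, at 21.2 ± 5.13 CPM in WT and 53.8 ± 25.8 CPM in cKO (SD, n = 3 each). The Wnt list (median 0.06, adjusted p = 0.879) held Axin1, whose log2 fold change was 1.55 with a standard error of 0.70, and 0.86 without cKO replicate 2. The Hedgehog and primary cilium lists had medians of -0.05 and -0.10 and means of 0.18 and 0.07, with camera directions below 0 (adjusted p = 0.879 and 0.963), and medians of 0.10 and 0.07 with library size as the scale. Axon guidance genes had 36 of 55 members above 0 and a median of 0.31 (adjusted p = 0.408). With GC and length trends removed, which moved the median of all tested genes to -0.09, the axon guidance and Notch medians were -0.01 and -0.07. Without single libraries the axon guidance median lay between 0.04 (without cKO replicate 2, where the test turned to lower) and 0.62 (without WT replicate 1), and that of Notch between -0.07 (without WT replicate 2) and 0.45. Spliceosome genes, of interest because PQBP1 binds the U5 protein Txnl4a, had 45 of 75 members below 0 and a median of -0.19 (adjusted p = 0.352). The spliceosome median was -0.01 without WT replicate 3 or cKO replicate 2, -0.48 without cKO replicate 3 and 0.05 with the batch term. Txnl4a had 421 ± 335 CPM in WT and 174 ± 63.1 CPM in cKO (SD, n = 3 each), with 793 CPM in WT replicate 2, without which its log2 fold change went from -1.28 to -0.52. Regulators of H3K4 and H3K27 methylation had a median of 0.04 (adjusted p = 0.9955), p53 targets 0.04 (0.963), stress response genes 0.10 (0.699) and glycolysis and hypoxia genes 0.09 (0.699). With upper-quartile factors the medians of the Wnt, methylation, p53 and glycolysis lists were -0.03, -0.06, -0.05 and -0.02. Without single libraries those of the p53, stress and glycolysis lists ranged from -0.40 to 0.39, -0.16 to 0.55 and -0.22 to 0.64. Ribosomal protein genes had a median of -0.08 (adjusted p = 0.105), which turned to 0.01 with library size as the scale. They were called lower with upper-quartile factors (median -0.19, adjusted p = 0.0463), without cKO replicate 2 (1.06e-10), WT replicate 1 (0.0368) or WT replicate 3 (0.01695), with the batch term (0.00211) and without both libraries numbered 2 (0.00142). Interferon-stimulated genes had a median of -0.39 (adjusted p = 0.779) and were called lower without WT replicate 2 (adjusted p = 0.00289) and without both libraries numbered 2 (median -0.75, 8.56e-05), while without WT replicate 3 the direction turned to higher (median 0.19, 0.607). The calls in this paragraph used the preset correlation of 0.01. In the main setting the estimated correlation was 0.28 for ribosomal protein and 0.31 for interferon-stimulated genes, with a camera adjusted p of 0.951 for both.

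Lists of other cells and of RNA quality were not called, and many of their values rested on single libraries. Endothelial and mural genes had 16 of 20 members above 0 and a median log2 fold change of 0.50 (adjusted p = 0.105), which was -0.07 without WT replicate 2 and -0.21 without both libraries numbered 2. Col1a1 had 20.7 CPM in cKO replicate 2 and at most 0.567 CPM elsewhere. Erythroid genes had a median of -0.38 (adjusted p = 0.105), with the haemoglobin gene Hbb-bs at 225 ± 90.0 CPM in WT and 130 ± 65.0 CPM in cKO (SD, n = 3 each). They were called lower without WT replicate 2 (adjusted p = 0.00101), with the batch term (0.0350) and without both libraries numbered 2 (median -0.07, 0.0497). Microglia genes had a median of -0.66 (adjusted p = 0.699) and C1qb reached 10.6 CPM. They were called lower without WT replicate 2 (adjusted p = 0.00101), which had the lowest microglia score, -2.05, and without both libraries numbered 2 (median -1.17, 4.15e-07). Without WT replicate 3 the direction of the microglia list turned to higher (median 0.35, adjusted p = 0.607). Astrocyte and oligodendrocyte lists had medians of 0.10 and 0.15 (adjusted p = 0.994 and 0.879), the former 0 with upper-quartile factors and -0.37 without cKO replicate 2. The oligodendrocyte median was -0.37 without both libraries numbered 2 and -0.26 with the replicate block. Immediate early genes had a median of 0.11 (adjusted p = 0.779), mitochondrially encoded genes -0.39 (0.300), nuclear RNAs -0.29 (0.352) and sex-linked genes 0.59, with a mean of -0.78 and a camera direction above 0 (0.105). Mitochondrially encoded genes were called lower without WT replicate 1 (adjusted p = 0.0143) or cKO replicate 3 (0.00745). Their direction turned to higher without cKO replicate 2 (median 0.07), without WT replicate 3 (0.37), without both libraries numbered 2 (0.27, adjusted p = 0.0927) and with the batch term (0.28). Nuclear RNAs were called lower without WT replicate 3 (adjusted p = 0.0490), while their median was -0.06 without cKO replicate 2. The calls in this paragraph used the preset correlation of 0.01. In the main setting the estimated correlation was 0.29 for erythroid, 0.25 for microglia and 0.72 for mitochondrially encoded genes, and 0.20 for nuclear RNAs. The camera adjusted p with it was 0.951 for each of these lists. The 33 lists that were not called had adjusted p from 0.105 to 0.9955, and across all 36 lists 0 members passed adjusted over the list alone.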

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

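The settings added after the data were examined number 4: without both libraries numbered 2, with a ribosomal RNA batch term, and with GC and length trends removed, without and with the replicate block. The count of changed genes stayed at 0 in every setting except 2. Without the low-count filter edgeR called 59 genes (54 higher, 5 lower), of which 16 were among the genes tested with the filter, and DESeq2 called 50 (45 higher, 5 lower), of which 42 had reads in 1 library. Leaving out single libraries gave 0 genes each time, with 0 higher and 0 lower. The Pqbp1 log2 fold change was above 0 in all 20 alternatives (0.09 to 1.44) and passed in none, with 0.12 to 1.44 when single libraries were left out. The number of lists called was 3, and became 0 with an estimated correlation, 0 with fry, 7 without both libraries numbered 2, and 1 to 5 without single libraries. The adjusted p of S phase was 0.951 with the estimated correlation and 0.970 with fry, which tests a list against no change and not against other genes, and 2.62e-05 to 0.0759 without single libraries. G2 and M phase had 0.951, 0.970 and 2.02e-07 to 0.0759. Oxidative phosphorylation had 0.951 and 0.970, 0.817 without both libraries numbered 2, 0.625 with the batch term, and 1.50e-13 to 0.999 without single libraries, the last without WT replicate 2, where the direction turned to higher. These calls were kept in 14, 15 and 12 of 18 alternatives, but with neither the estimated correlation nor fry. The estimated inter-gene correlations were 0.07, 0.19 and 0.43, above the preset of 0.01 that all other alternatives kept. The tally therefore does not test that preset. The cause of the losses was not tested. Upper-quartile factors moved the median log2 fold change of all tested genes from 0.01 to -0.09 and library size alone to 0.10. The called lists kept their direction under both.

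The replicate number as a block left 0 genes called and the number of lists at 3. Deviations from the group means correlated at 0.09, 0.03 and 0.37 for numbers 1, 2 and 3, and not every library correlated best with its own number. However, the smallest chi-square per degree of freedom of all pairs were those of the libraries numbered 3 (88.7) and 1 (116). That of the pair numbered 2 was 529. Whether the numbers pair libraries is therefore not settled. Across all settings 100 of 3146 values of named genes and 90 of 647 of lists changed sign, of which 1, oxidative phosphorylation, belonged to a called list, and 17 list calls were made that the main setting did not make. Of the named genes, Hist2h2aa1 and Ccnk passed in DESeq2 and in edgeR without the filter. Spread between libraries limits the test: the common biological coefficient of variation was 91.5%.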

Other observations

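The test of GC content and length was fixed before its result was computed. The tests of single libraries, within-batch scores, silent genes, Pqbp1 and divisions of the libraries were chosen after the values they use, or part of them, had been seen.

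Transcripts that mark regions beside the lateral ganglionic eminence were detected in the sorted cells, and none of their lists was called. Nkx2-1, the factor of the medial ganglionic eminence, averaged 39.1 ± 25.7 CPM in WT and 20.1 ± 5.92 CPM in cKO (SD, n = 3 each), with 68.7 CPM in WT replicate 2, and Lhx6 61.6 ± 20.6 CPM and 41.0 ± 12.02 CPM. The list of the medial eminence and interneurons had a median log2 fold change of -0.12 (camera adjusted p = 0.385; -0.46 to -0.14 without single libraries), and 0.03 with library size as the scale. Those of the dorsal lateral eminence and the caudal eminence had medians of -0.26 and 0.33 (adjusted p = 0.699 and 0.933), the latter -0.28 with GC and length trends removed. Without single libraries they lay between -0.44 and 0.29 and between -0.04 and 0.68. Of the cortical excitatory list, Cux2 and Tle4 averaged 31.5 and 50.1 CPM in WT and 44.2 and 71.3 CPM in cKO, Neurod6 lay at or under 2.94 CPM in all 6, Tbr1 had 10.2 CPM in WT replicate 2 and at most 1.61 CPM elsewhere, and the list had a median of -0.17 (adjusted p = 0.699), which was 0.55 without WT replicate 1 and 0.24 without cKO replicate 2. Dopamine receptor transcripts of mature striatal neurons were low, with Drd1 at 3.50 ± 2.69 CPM in WT and 1.75 ± 1.59 CPM in cKO and Drd2 at 1.995 ± 1.73 CPM and 3.21 ± 2.63 CPM (SD, n = 3 each).

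T cell receptor variable genes, chosen after their values were seen, had reads for more genes in cKO replicates 1 and 2 than in the other libraries, in the Trbv and Trav families. Of 22 genes of the Trbv family, 18 had reads in cKO replicate 1 and 19 in cKO replicate 2, against 2 in WT replicate 1, 1 in WT replicate 3 and 0 in the others. Of 73 genes of the Trav family, 17 had reads in WT replicate 1, 7 in WT replicate 3, 32, 56 and 5 in cKO replicates 1, 2 and 3, and 0 in WT replicate 2. Other silent families did not share this order. Of 38 immunoglobulin genes of the Ighv family, 26 had reads in WT replicate 1, and 9 and 8 in cKO replicates 1 and 2. Of 45 genes of the Igkv family these libraries had 25, 10 and 4, and of 741 olfactory receptor genes 523, 381 and 87. WT replicate 1 was the highest of all libraries in each of these families. No test between the labels was run on these values.

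The lower S phase and G2 and M phase genes in the libraries labelled cKO form the first pattern weighed. With GC and length trends removed the median log2 fold change of the 106 members was -0.49 with a bootstrap SD of 0.05, against -0.40 before. The median of all tested genes moved from 0.01 to -0.09, so relative to it the members hardly moved. Bootstrap SDs here are over members that share the same libraries and do not measure the spread between libraries. The values argue against those trends as the whole cause in these libraries. Without cKO replicate 2 the median was -0.16 with an SD of 0.03, between the bounds set for that library being the cause or not. A lower share of cycling cells remains a hypothesis. The score of cKO minus WT was 0.05 with a standard error of 0.06 over genes in the low ribosomal RNA batch and -0.54 in the high batch. Without WT replicate 2 the low-batch scores were -0.22 for S phase and -0.26 for G2 and M phase. Without cKO replicate 2 the high-batch scores were -0.04 for both. Each batch has 1 library on one side, so the hypothesis cannot be told apart from differences between single libraries.

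Reads in olfactory and vomeronasal receptor genes, silent in the brain, form the second pattern and took 395 and 897 CPM in WT replicate 1 and cKO replicate 2, 116 CPM in cKO replicate 1, and 11.7 to 34.05 CPM elsewhere. Sequencing depth is argued against, since WT replicate 1, with 12263846 counts, had 734 receptor genes with a read, 3.06 times those of the deepest library, and since cKO replicate 2, with 146 such genes against 240 there, had 27.2 times its share of counts in them. Genomic DNA may contribute: in WT replicate 1 silent X-linked genes had 0.540 times the reads per kb of silent autosomal genes (bootstrap 95% interval 0.364 to 0.758), where a male has 1 X and a pair of each autosome, but the interval reaches past the bound of 0.75 set for it and the question stays open. In cKO replicate 2 the ratio was 0.586 (0.181 to 1.21), with a median of 12 counts per detected receptor gene against 4 in WT replicate 1. The ratio was 0.673 (0.403 to 1.055) in cKO replicate 1. Genomic DNA should also give reads in every silent family. In WT replicate 1 each family examined had reads, but unevenly, from 2 of 22 Trbv genes to 523 of 741 olfactory receptor genes. In cKO replicate 2 none of 9 taste receptor genes (Tas2r) had a read. No biological explanation was tested.

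The level of Pqbp1 in the libraries labelled cKO forms the third pattern. WT replicate 2 had high Xist and no Y-linked reads, unlike the males its label describes. The labels describe males in both groups, so this does not show whether its group label is wrong. Without WT replicate 2 the log2 fold change of Pqbp1 was 0.12 with a standard error of 0.70. That leaves open whether a wrong group label of this library accounts for the pattern. An exchange of the labels between the groups would put every WT library below every cKO library, and 2 of 3 were. WT replicate 3, with the highest level of all, is a single library and excludes nothing. Reads from exons outside the deleted part would also keep the level up, and counts per gene cannot test this.

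Other divisions of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real division gave 0 genes past the threshold and the highest of the others also 0, so all 10 reached it. Any division reaches a count of 0, so this comparison can decide nothing. At an unadjusted p under 0.05 it gave 143 genes, 9 of the 10 divisions gave at least as many, and the highest gave 2231. That highest division set WT replicate 1, cKO replicate 1 and cKO replicate 2 against the rest, which is the division by ribosomal RNA content. A division of WT replicates 1 and 2 and cKO replicate 2 against the rest gave 1466. Both cross the labels, only the former follows ribosomal RNA content, and neither gave a gene past the threshold. With the ribosomal RNA batch as a term, 48 genes had an unadjusted p under 0.05 between the labels and 0 passed. For gene lists the real division called 3, 7 of the 10 called at least as many, the highest called 10, and the division by ribosomal RNA content called 5. That division gave a camera p of 1.88e-06 for G2 and M phase and 1.81e-04 for S phase, against 2.59e-06 and 9.92e-05 for the real one. For oxidative phosphorylation it gave 9.05e-14, against 6.87e-06, and the smallest of all divisions was 1.23e-16.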
